A study of Caenorhabditis elegans with 4 samples.

How the data were processed

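NHR-237, a member of the nuclear hormone receptor family of transcription factors, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the nematode Caenorhabditis elegans. Per the labels' protocols, hermaphrodites of strain OP228 carried a GFP-tagged nhr-237 transgene, were grown at 20 °C to the L3 larval stage and were fixed with 2% formaldehyde. Chromatin was sonicated and the tagged protein was collected with an anti-GFP antibody, while a part of the same lysate was kept as input DNA. The series held 4 samples, namely 2 NHR-237 ChIP samples and 2 input samples, numbered as replicates 1 and 2 in each group. Samples were assigned to groups from their titles.

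The authors deposited 3 peak lists, 1 for each ChIP sample and 1 combined list over both. Per the file headers, positions refer to the WormBase WS220 genome build. Per the source column of the deposited files, peaks were called with SPP through an irreproducible discovery rate procedure (IDR). IDR is meant to keep peaks whose ranking recurs between replicates, and how it was applied to the replicate lists was not established. In each replicate list 45.8% of the peaks overlapped a peak of the other, which argues against a filter on recurrence between these 2 lists. The aligner, the SPP version, the threshold, the use made of the input samples and the way the combined list was assembled are not given in the sources used here. Each deposited peak carries a score, whose unit and meaning are likewise not given in the sources used here, and a name with a number counted from 1 within its list. This is called the peak number here. The authors' score was used to rank or divide peaks within a list, to compare the order of overlapping peaks between replicates by a rank correlation, and, in the closing observations, to examine how the score relates to the peak number. It did not fall steadily with the peak number: it was tied at its maximum over the first peaks, fell below 0 and then returned toward 0. The score was kept as the first ranking, as set at the outset, and the peak number was added as a second ranking after the data were seen. No read counts were used, so the sequencing depth behind each list is unknown and no value per peak carries a counting error. Intervals on shares of peaks are exact 95% Clopper-Pearson intervals and cover the number of peaks only. No peak list of an input sample was used here.

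Replicate lists were compared by the share of peaks in one list that had at least 1 bp in common with a peak of the other. The comparison level came from 1000 circular shifts of the list whose share was measured, with the other list kept in place. Every peak was moved by 1 random distance per chromosome, so that widths and spacing were kept. The p-value was one-sided, and 0.001 is the smallest the shifts can give. Overlap was also computed for the 100, 500, 1000 and 5000 peaks of highest score in each replicate, and for each of 10 equal score classes. Scores of one-to-one overlapping peaks were compared by Spearman's rho with a two-sided permutation test of 100000 resamples, for which 1e-05 is the smallest possible p. Chromosome counts of combined peaks were compared with chromosome length by a two-sided exact binomial test for X. A Pearson chi-square test over the 6 chromosomes was added, with its p taken from 100000 Monte Carlo multinomial draws. Peak midpoints were also divided into 3 equal parts of each chromosome, and the central part was tested with a two-sided exact binomial test. Chromosome length was taken as the end of the last replicate peak on each chromosome, which gave a summed span of 100.2 Mb.

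Alternatives fixed before the data were examined were overlap of at least 50% of both peaks, midpoints within 100 bp, the higher-scoring peaks of each list (45 combined peaks and 15000 peaks of each replicate), pooled replicate peaks as the background for chromosome counts, and the leading 89 peaks of a single replicate in place of the combined list. Ranking by peak number, shifts of 5 to 20 kb, merging of overlapping combined peaks, tests of each chromosome with Benjamini-Hochberg adjustment over the 6, the difference between the first and last score class, and the division of combined and leading replicate peaks by maximum score were added after the data were seen. Statistics were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The procedures were tested on simulated data. In the overlap test, 40% of 5000 simulated peaks were planted as shared. After correction of the observed share for the shifted level, the estimate was 39.6%. Shares in the real lists are given without this correction. Of 100 pairs of independent simulated lists, 2% passed p of 0.05. The rate of false positives for lists with the number and spacing of the real peaks was not measured. Pairing of overlapping peaks recovered 99.2% of 2000 planted pairs, and Spearman's rho came out at 0.256 in 2000 simulated pairs drawn from a distribution with a rho of 0.288. With 89 peaks and 30% planted on X, the binomial test called X in 76.6% of simulations, against 3.6% with none planted.

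Planned tests of promoter location, of gene lists, of the nhr-237 and unc-119 loci carried by the transgene, and of sequence motifs were to be run only with a reference of the WS220 build. No genome or annotation of that build was used here, so these tests were not run and peaks are named by position alone. The rule for naming peaks, fixed at the same time, takes the 10 combined peaks of highest score. Because 16 were tied at the maximum, those with the lowest peak numbers were taken.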

Results

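Regions bound by NHR-237 were mapped at the L3 larval stage in a strain whose nhr-237 transgene is fused to GFP. NHR-237 belongs to the nuclear hormone receptors, a family of DNA-binding transcription factors that is much enlarged in nematodes. Immunoprecipitation with an anti-GFP antibody was carried out on 2 samples, each with an input sample of the same replicate number. Peak positions and scores were read from 3 lists made by the authors, 1 per ChIP sample and 1 combined list. Depth could not be read from these lists and is unknown. Tests were made over peaks within these samples, and nothing states that the replicates came from separate cultures. The p-values therefore cover chance in the placement, order or number of peaks within these samples, not the spread between cultures, and differences between the replicates may be technical.

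The combined list held 89 peaks, each 520 bp wide, which together covered 0.0459% of the genome span. Each replicate list held 30000 peaks, the same number in both, and whether this number was a preset limit was not established. Peaks were 490 bp wide in replicate 1 and covered 13.7% of the span. In replicate 2 they were 480 bp wide and covered 13.5%. A maximum score was shared by 17 peaks in replicate 1 (1.52), by 16 in replicate 2 (1.49) and by 16 in the combined list (1.49). Below these leading peaks the score dropped quickly, passing under 0 at peak number 55 in replicate 1, 33 in replicate 2 and 32 in the combined list. It reached its lowest value, -0.181, at number 122 in replicate 1, -0.247 at number 80 in replicate 2 and -0.572 at number 62 in the combined list. In the replicate lists it then climbed back toward 0, so that beyond the leading peaks a high score and a low peak number did not mark the same peaks. A score above 0 was held by 31 of the 89 combined peaks, 4185 peaks of replicate 1 and 30 peaks of replicate 2. Most of the 4185 were late-numbered peaks with scores barely above 0, such as 0.000416 at number 26123 and 0.00283 at number 30000.

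**Figure D1:**
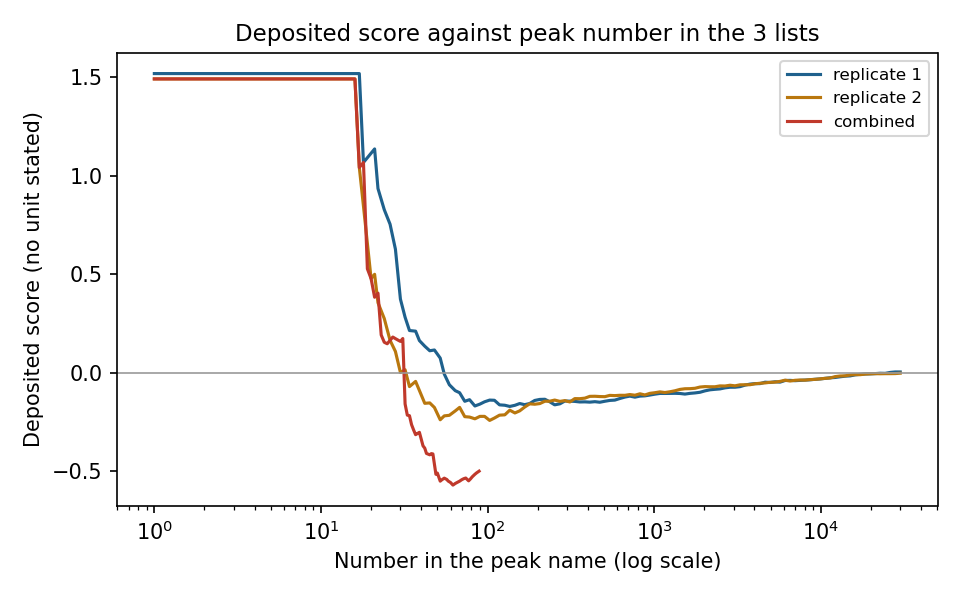
The authors' score (vertical axis, no unit stated) is plotted against the number in the peak name (horizontal axis, log scale), with 1 line for each of the 3 peak lists. All 3 lines start at a flat maximum of 1.49 or 1.52 and drop below 0 before peak number 60, and both replicate lines return to near 0 by number 30000 while the combined line ends at -0.501.

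The first question was how far the replicates located the same regions. Of the 30000 peaks of replicate 1, 45.8% overlapped a replicate 2 peak, and 45.8% of replicate 2 peaks overlapped a replicate 1 peak. Shifted lists overlapped in 25.7% ± 0.279 (SD over 1000 shifts) and 25.7% ± 0.271 of peaks, so the observed shares were 1.78-fold higher in both directions. None of the shifts exceeded 28.5% (circular-shift permutation test, one-sided p = 0.001 in both directions, the smallest the shifts can give). Because each list covered more than 13% of the span, many peaks met a peak of the other list by position alone. With midpoints required to lie within 100 bp, 23.3% of the peaks in either direction were shared, against 6.01% after shifting. Among the higher-scoring 15000 peaks of each list, 21.6% of replicate 1 peaks were shared, against 13.7% after shifting. Beyond the leading peaks, these sets held mostly late-numbered peaks. They were bounded by the median score, -0.0167 in replicate 1 and -0.0133 in replicate 2. At number 15019 the scores were -0.0171 and -0.0125.

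At equal list lengths, the 100 peaks of highest score supplied most of the regions shared at 500 and at 1000 peaks. Of the 100 peaks with the highest scores in each replicate, 21 were shared, against a mean of 0.135% after shifting. Extending the lists added few shared regions at first: 23 of 500 peaks (4.6%, shifted 0.469%), 31 of 1000 (3.1%, shifted 0.954%) and 376 of 5000 (7.52%, shifted 4.74%). Peaks added by score were mostly late-numbered, because scores near 0 lay late in each list. In replicate 1 the score was 0.00288 at number 27995, against -0.146 at number 506. In replicate 2 it was -0.00352 at number 30000, against -0.123 at number 506. All 4 list lengths gave a one-sided circular-shift permutation p of 0.001, the smallest the shifts can give. Ranking by peak number, chosen after the data were seen, gave more shared regions at every length, with 29 of 100, 53 of 500, 109 of 1000 and 862 of 5000. The order of the peaks therefore moved the count more than 1.5 times at 500 peaks and beyond.

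Regions found in both replicates held only weakly related scores. Across 11940 one-to-one overlapping pairs, Spearman's rho was 0.116 (two-sided permutation p = 1e-05, the smallest the permutations can give). This correlation is across peaks, which are not independent replicates. It was not detected among the 3062 pairs drawn from the higher-scoring 15000 peaks of each list, where rho was 0.00478 (two-sided permutation p = 0.792). Beyond the leading peaks, those sets held mostly late-numbered peaks, so this rho does not describe the early-numbered ones. Peak numbers, a ranking added after the data were seen, were also only weakly related. Across the same 11940 pairs their rho was 0.126 (two-sided permutation p = 1e-05, the smallest the permutations can give).

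Share by score class ran opposite to the score. In the class of highest score (3000 peaks), 38.7% of replicate 1 peaks were found in replicate 2, and in the class of lowest score 59.7% were. Replicate 2 peaks gave 37.9% and 59.8%. The mean over shifted lists lay between 25.6% and 25.8% in every score class, single shifts reached at most 31.9%, and all observed shares exceeded every shift of their class (one-sided circular-shift permutation p = 0.001 in each class, the smallest the shifts can give). Sorting by peak number, chosen after the data were seen, turned the direction: 60.6% of the first 3000 replicate 1 peaks were shared and 38.2% of the last 3000, with 60.2% and 37.7% for replicate 2. The lowest scores lie at low peak numbers, where the score dips below 0.

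**Figure D2:**
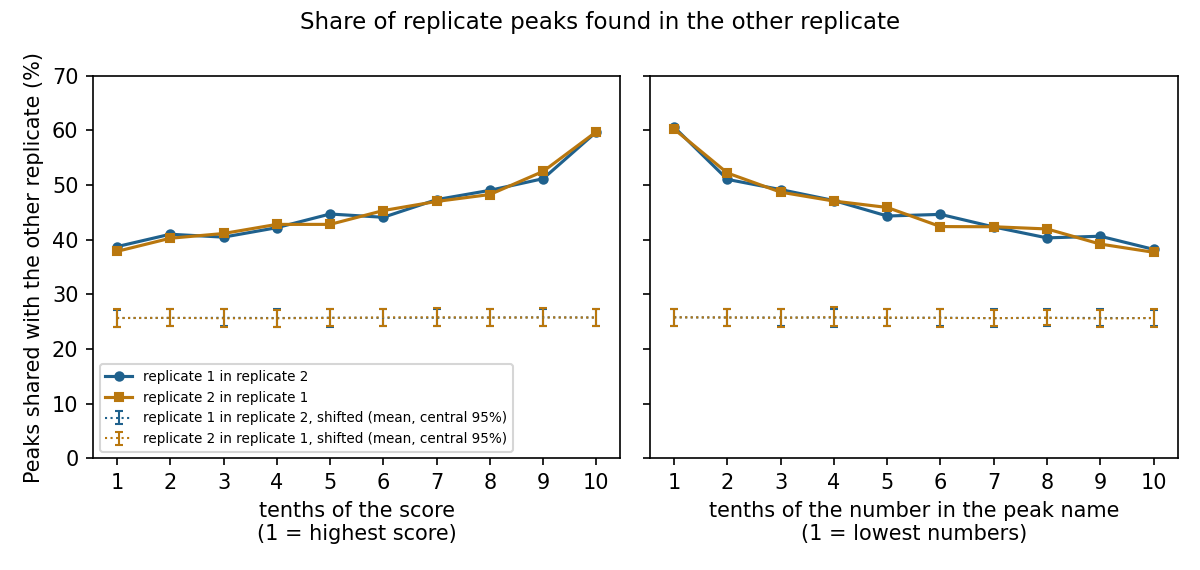
The share of replicate peaks found in the other replicate (vertical axis, percent) is shown in 10 equal classes of 3000 peaks, ordered by score on the left and by peak number on the right; solid lines are observed shares and dotted lines are means of 1000 shifts with their central 95% range. Replicate 1 peaks climb from 38.7% to 59.7% along the score classes and fall from 60.6% to 38.2% along the number classes, and both stay above the shifted level near 25.7%.

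All 89 combined peaks overlapped a peak in both replicates, also when at least 50% of both peaks had to be shared. When the combined peaks were shifted, a mean of 27.1% of them met a replicate 1 peak and 26.8% a replicate 2 peak. This is not independent evidence, since the combined list was made from the same libraries. The matching peaks had a median peak number of 98 in replicate 1 and 124 in replicate 2. The 14 combined peaks on X with the maximum score matched early peaks, with a median number of 7.5 in each replicate. The other 12 on X had medians of 67.0 and 220.0, and the 61 autosomal peaks under the maximum had medians of 214 and 176. Division by maximum score was made after the values were seen. Peaks numbered within the first 100 of both replicates accounted for 29 combined peaks, of which 17 lay on X, including a pair of overlapping combined peaks that matched the same replicate peaks. Conversely, 20 combined peaks, 17 of them autosomal, matched a peak numbered beyond 1000 in at least 1 replicate. The 58 combined peaks scoring below 0 had median numbers of 259 and 207.5, and 3 of them were within the first 100 in both replicates.

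**Figure D3:**
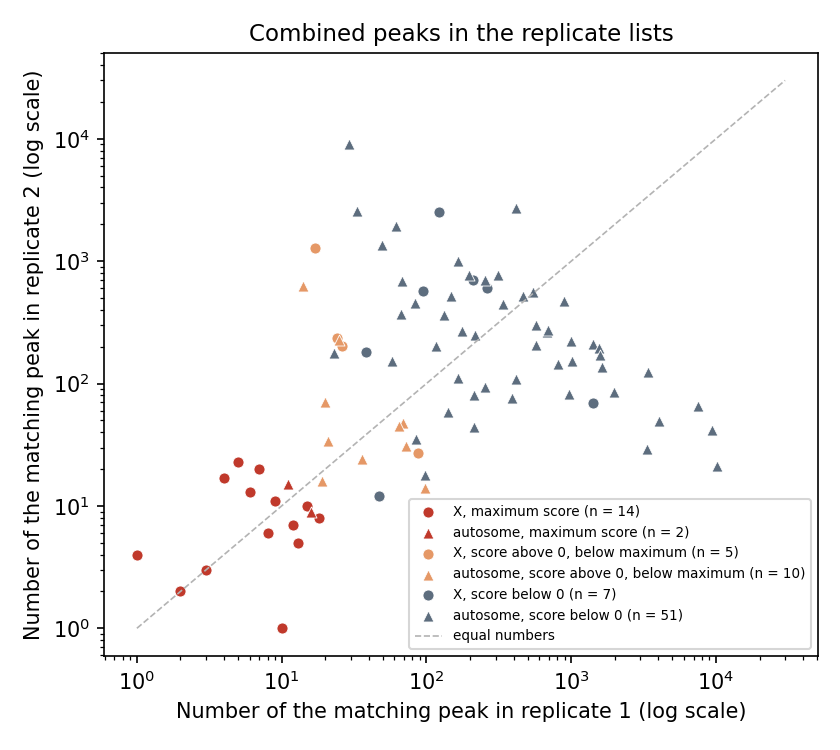
Each of the 89 combined peaks is plotted by the number of its matching peak in replicate 1 (horizontal axis, log scale) and in replicate 2 (vertical axis, log scale), with circles for X, triangles for autosomes and color for the combined score. The 16 maximum-score peaks occupy numbers 1 to 18 in replicate 1 and 1 to 23 in replicate 2, and the peaks scoring below 0 spread to numbers 10208 and 8984.

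The leading combined peaks lay on the X chromosome. All 10 peaks named by the fixed rule were there, each at the maximum score of 1.49, with positions on the WS220 build. Peak 1 was at X:11093919-11094438, peak 2 at X:9465540-9466059 and peak 3 at X:13700551-13701070, and these matched replicate peaks numbered 1 and 4, 2 and 2, and 3 and 3 in replicates 1 and 2. Peaks 4 to 6 were at X:6296308-6296827, X:16056285-16056804 and X:2996894-2997413. Peaks 7 and 8, at X:806430-806949 and X:14525614-14526133, ranked earlier in replicate 1 (numbers 4 and 7) than in replicate 2 (17 and 20). Peaks 9 and 10 were at X:5429312-5429831 and X:4208998-4209517. Among the 16 peaks tied at the maximum, 14 were on X, and the other two, picked out after their values were seen, were at III:3867303-3867822 and II:10563242-10563761. What the annotation holds at these positions was not analysed here.

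X held more of the combined peaks than its length predicts, and chromosome V held fewer. On X there were 26 of 89 peaks (29.2%, 95% Clopper-Pearson interval 20.1 to 39.8), against 17.7% or 15.7 peaks by length, a ratio of 1.65 (two-sided exact binomial p = 0.00761). On V there were 8 peaks (8.99%, interval 3.96 to 16.9) against 20.9% by length (two-sided exact binomial p = 0.00388). After Benjamini-Hochberg adjustment over the 6 chromosomes, a step chosen after the data were seen, adjusted p was 0.0228 for both X and V. Chromosomes II, III, IV and I held 18, 14, 14 and 9 peaks and did not pass (adjusted p from 0.353 to 0.780). The distribution over all 6 chromosomes departed from length (Pearson chi-square test with Monte Carlo multinomial draws, p = 0.00675). In the full replicate lists X held 20.0% (replicate 1) and 19.7% (replicate 2) of peaks, and V held 21.2% and 20.9%. Against the pooled replicate peaks as background the X share passed less clearly (two-sided exact binomial p = 0.0331).

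In the combined list, the excess on X was carried by the peaks of maximum score, a division made after the values were seen. Of the 16 maximum-score peaks, 87.5% were on X (95% Clopper-Pearson interval 61.7 to 98.4). Of the other 73 combined peaks, 12 or 16.4% were on X (interval 8.79 to 26.95), close to the 17.7% given by length (two-sided exact binomial p = 0.879). The odds ratio between the sets was 35.6 (two-sided Fisher's exact p = 1.1e-07). The maximum-score peaks of each replicate alone also lay mostly on X, at 14 of 17 in replicate 1 (82.4%) and 12 of 16 in replicate 2 (75.0%). In replicate 1 the excess also extended under the maximum: of the remaining 72 among its leading 89 peaks, 21 were on X by score (29.2%, two-sided exact binomial p = 0.0190) and 23 by peak number (31.9%, two-sided exact binomial p = 0.00299). In replicate 2 the remaining 73 gave 18 (24.7%, two-sided exact binomial p = 0.125) and 12 (16.4%, two-sided exact binomial p = 0.879). The sets by score also include late-numbered peaks with scores near 0, since the score passed under 0 at number 55 in replicate 1 and 33 in replicate 2.

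**Figure D4:**
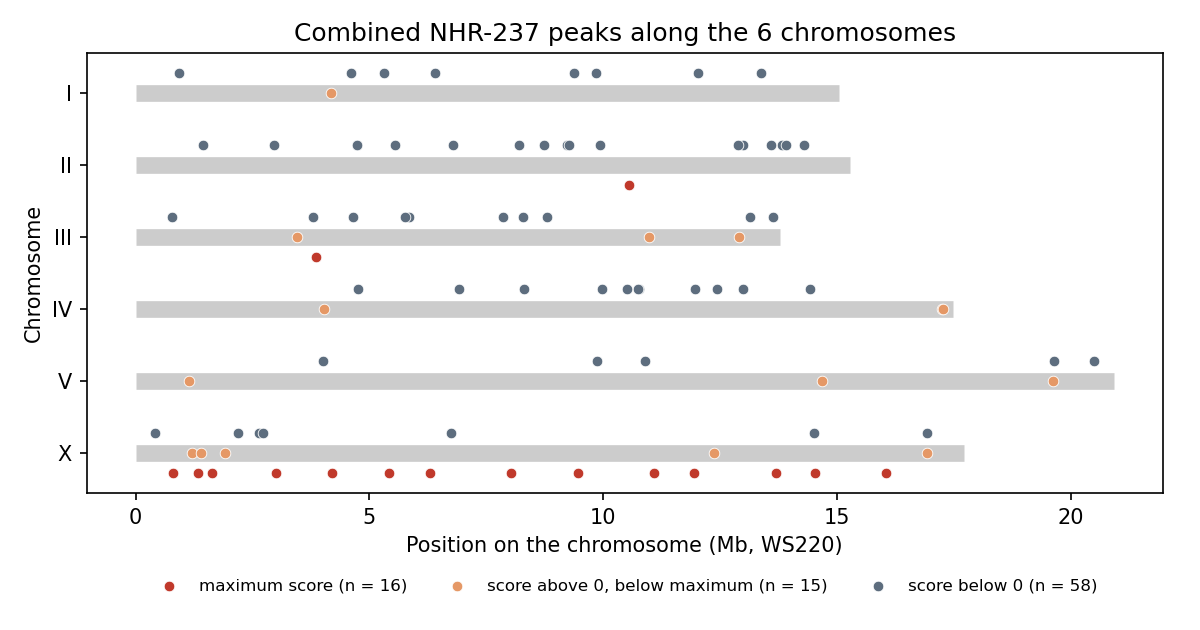
The 89 combined peaks are drawn along the 6 chromosomes (horizontal axis, position in Mb on WS220; gray bars run to the last replicate peak), with maximum-score peaks under each bar, peaks scoring above 0 on it and peaks scoring below 0 over it. The 14 maximum-score peaks on X run from 0.807 to 16.1 Mb, and the remaining 2 lie on II and III.

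Combined peaks showed no preference for chromosome centers that could be detected with this number of peaks. The central part of the chromosomes, 1 of 3 equal parts, held 30 of 89 peaks (33.7%, 95% Clopper-Pearson interval 24.0 to 44.5) against 33.3% by length (two-sided exact binomial p = 1). The full replicate lists placed 36.7% (replicate 1) and 37.4% (replicate 2) of their peaks there. Among the 45 combined peaks of higher score the share was lower, at 22.2% (two-sided exact binomial p = 0.153), and this difference did not pass the test either.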

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

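Ranking or sorting by peak number, shifts of 5 to 20 kb, merged peaks, the replicate share as the reference for chromosome centers and the first-minus-last class difference were chosen after the data were seen; the other alternatives were planned. Of 51 alternatives to 19 results, 37 with a test kept direction and side of the threshold, 24 of them overlap shares at the smallest p the shifts can give, where the share itself could still move. A further 5 without a test kept direction or value; for the 89 combined peaks, leaving out a replicate could not change the count. Taking the higher-scoring peaks of each list left 45 combined peaks and 15000 in each replicate, by construction. The 15000 of each replicate are the leading peaks and otherwise mostly late-numbered ones. Among them the rank correlation of shared peaks fell to 0.00478, a value that does not describe the early-numbered peaks. The cause was not tested. The share of combined peaks in chromosome centers, which passed the test in none of its alternatives, changed side of its expected value 3 times: at 22.2% in the higher-scoring peaks, at 33.7% against the replicate share of 37.1%, and at 30.3% in the leading 89 peaks of replicate 1 by peak number. Single replicates gave 30.3% to 38.2% there and 26.97% to 41.6% on X. Sorting by peak number turned the first-minus-last class difference in replicate overlap from -21 to 22.4 points (replicate 1) and from -21.9 to 22.5 (replicate 2), and raised the shared peaks from 23 to 53 of 500, 31 to 109 of 1000 and 376 to 862 of 5000. All tested overlap shares stayed above their shifts (one-sided circular-shift permutation p = 0.001). No paired analysis was possible because no peak list of an input sample was used here, so no comparison between groups was made. Separate ranking by p- or q-value was not run, since no value in the lists is named as either. Whether the score is itself a value of that kind was not established. Alternatives for promoters, gene lists and motifs were not run without a WS220 reference. Unknown depth limits any statement on peaks missing from a list.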

Other observations

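The tests of the X-linked peaks, of the score formula and of overlap among peaks numbered above 1000 were chosen only after the results were seen.

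Most maximum-score combined peaks lay on X, 14 of 16. Replicate peaks outside the combined list were also more frequent on X than its 17.7% of the span, at 20.0% and 19.7% (two-sided exact binomial p = 9.42e-25 and 1.18e-19). These p-values treat peaks as independent, though the 30000 peaks of each list merge into 25796 and 25862 regions. A rise of this size, acting alike on all peaks, lies far below the lower bound of 61.7% for the maximum-score peaks. It would leave most of their excess unaccounted for. Because these sets are nearly the full replicate lists, their shares cannot speak about an X background confined to the strongest peaks. A single local stretch, such as a duplicated segment, would place them together, but they fell in 12 windows of 1 Mb (the central 95% of 10000 random placements on X ran from 8 to 12), with a median gap of 1.22 Mb and a smallest gap of 282 kb. They did not come from 1 replicate alone either, since the lower X share among a replicate's own maximum-score peaks was 75.0%. A hypothesis that stays open is that dispersed X-linked elements, such as the sites that recruit the dosage compensation complex, are the strongest regions in this precipitate, which may reflect binding by NHR-237 or recovery of such sites whatever the tagged protein; no biological explanation was tested, as no list of these sites and no untagged or other GFP strain was used here.

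Scores fell below 0 soon after the leading peaks. With i the peak number, the score was set equal to log10((i - 0.5)/(c + 0.5)), and this was solved for c. The solved c lay within 0.001 of a whole number in 98.16% of replicate 1 peaks and 98.09% of replicate 2 peaks. With the numbers shuffled, this held for 0.31% or less of the peaks of each replicate. It also held for all 73 combined peaks under the maximum score. Of the peaks tied at the maximum it held for 1 in each list, that of the highest number. At combined peak 16 c was 0, at peak 30 it was 20, and at peak 89 it was 280, so a score below 0 means that c has reached or passed the peak number; c may be the number of peaks at the same height in a reference such as the input, which the lists alone do not show. The overlap of the full lists, of which most peaks are numbered above 1000, already shows that lower peaks were not placed independently in the replicates, and with the leading peaks left out 43.7% of the 29000 replicate 1 peaks numbered above 1000 overlapped such replicate 2 peaks, against at most 27.6% in 1000 shifts along the chromosome and 26.8% in shifts of 5 to 20 kb. Whether this recurrence comes from weak binding or from background common to both libraries stays open, since no input peak list was used here.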
